A study of Marchantia polymorpha with 12 samples.

How the data were processed

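RNA from thalli of the liverwort Marchantia polymorpha was sequenced in 12 libraries. The labels name 4 groups of 3 libraries: the male laboratory accession Tak-1 and the line Mperf15ko, each as intact control thalli and as thalli collected 1 h after their blades were wounded. Thalli were 14 days old. Per the labels' protocols, each replicate was an independent biological replicate of 12 plants, RNA was extracted with a column kit, and libraries were made with the TruSeq Stranded mRNA kit. The labels do not describe the lesion of Mperf15ko, so groups are called by their labels throughout.

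Per the file headers, each deposited file was a Salmon table with 1 row per transcript, giving its length, its effective length, its TPM and its estimated count of reads. The submitters' processing notes name CASAVA and Salmon 0.7.2 without their roles. The genome build, the transcript annotation, the index and the Salmon options are not given in the sources used here. Each file listed 24751 transcripts. The deposited TPM values were scaled to a constant total in every library, and the deposited estimated counts were fractional for 32.8% to 37.6% of transcripts per library. Effective lengths were identical in all 12 files.

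Estimated counts were summed over the transcripts of each gene, giving 19421 genes, of which 16390 had 1 transcript, and were rounded to whole numbers. Totals per library ranged from 17.2 to 30.4 M estimated reads. After edgeR's filterByExpr by group, 14246 genes were tested. Scaling used TMM. The 4 groups were fitted as cell means over all 12 libraries with edgeR 4.0.16 (glmQLFit, robust, and glmQLFTest) in R 4.3.3, without a covariate. The common biological coefficient of variation was 0.126. Genes with a Benjamini-Hochberg adjusted p under 0.05 were called, and every adjusted p for a gene comes from edgeR unless another tool is named. Standard errors were derived from the fitted log2 fold changes and the test statistics. CPM values were scaled with the TMM factors and are given as mean ± SD over the 3 libraries of a group.

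The 5 contrasts tested were the wound response in each genotype, the difference of Mperf15ko from Tak-1 in control and in wounded thalli, and the difference between the wound responses (Mperf15ko minus Tak-1). The size of the wound response was compared over genes called by the mean of both wound responses, a contrast orthogonal to the difference between them, and a score per wounded library, minus the mean score of the controls of its genotype, was compared by an exact 2-sided permutation test. The pipeline was tested on simulated counts drawn from the means, fitted dispersions and library sizes of the 14246 genes. Recovery was measured only for genes with an average CPM of 4 or more. Among these, 200 genes were changed in 1 group by known folds, 50 of them by each of 1.5-, 2-, 4- and 8-fold. The shares recovered, in that order of folds, were 66%, 92%, 100% and 100% for the wound response in Tak-1, and 78%, 88%, 100% and 100% for that in Mperf15ko. They were 72%, 90%, 100% and 100% for the genotypes in control thalli, 72%, 94%, 100% and 100% for the genotypes in wounded thalli, and 42%, 72%, 96% and 100% for the difference between the wound responses. Between 4 and 13 unchanged genes were called per contrast. Far more genes than 200 were called in the data for each wound response and genotype comparison, so these shares need not hold there.

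Gene names came from a table of the reference assembly MpTak2_v7.1, made from the female accession Takaragaike-2, which was used for names and for the order of genes. Of the 19421 gene IDs, 17386 (89.5%) matched a locus tag, and 3091 had a symbol. Lists of gene families had been defined by protein signatures. Without a genome sequence they were filled from the symbols, which served 27 lists and left 6 void: allene oxide cyclase, OPDA reductase-like, HSP70, small HSP, EF-hand and light-harvesting proteins. A further 14 lists were added from the symbols before expression values were looked at: LEA, dirigent, PR1, GST, UGT, MCM, DOXC, terpene synthase, auxin, jasmonate signalling, trihelix, ASLBD, ABCG and PPR genes. A symbol covers part of each family, so a list is not a census of it. For each list, members called over all genes were counted, and again with p-values adjusted over the list alone. Lists with 5 or more tested members were compared with all other genes by limma's camera with a preset correlation of 0.01, adjusted over the 35 lists tested per contrast, and again with an estimated correlation. With the preset correlation 7, 9, 18, 13 and 5 lists were called in the 5 contrasts in the order above. With the estimated correlation camera called 0 lists in each contrast, with 3, 1, 7, 6 and 2 lists at an unadjusted p under 0.05, and fry called 81 over all contrasts.

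Groups, contrasts, tests, the first set of lists, the alternatives and the rule for naming genes were fixed before the data were examined. The rule took MpERF15, every tested lipoxygenase, CYP74 and TIFY gene, up to 2 called members of each other list with the largest absolute log2 fold change at an average log2 CPM of 2 or more, the 5 highest and 5 lowest called genes of each contrast whose groups did not overlap, and fixed markers of cell types. For the difference between responses, no overlap condition was used. Genes without a symbol are given by ID, at most 2 per direction.

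Of the 14246 tested genes, 9556 had whole estimated counts in every library, within a tolerance of 0.01. The others carried fractional counts, which Salmon gives where reads match more than 1 transcript, so values of close family members are uncertain. Among the 210 named genes, 115 had whole counts. Counts were assigned by the authors' Salmon run, and whether it used strand is not given in the sources used here.

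Alternatives were RLE and upper quartile scaling, no filter beyond 1 read, a stricter filter of 5 CPM in 3 libraries, unrounded counts, effective length offsets, transcripts as features, only the libraries compared, no genes of the male sex chromosome, the replicate number as a block, each library left out in turn, DESeq2 1.42.0, voom and trend tests of limma 3.58.1 (the latter on log2(TPM + 1)), and an added threshold of 2-fold. Python 3.11.15 with pandas 2.3.3, numpy 2.4.6, scipy 1.17.1 and matplotlib 3.10.9 was used for preparation and figures. Raw reads, the sequence of the mutant allele and plant phenotypes were not analysed here.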

Results

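Transcript abundance was measured in thalli of Marchantia polymorpha from Tak-1 and from the line labelled Mperf15ko, either intact or collected 1 h after wounding, with 3 libraries in each of the 4 groups. Estimated reads came to 30.4, 21.2 and 24.5 M in the Tak-1 control libraries (replicates 1 to 3), and to 17.8, 23.3 and 24.6 M in the wounded Tak-1 libraries. They came to 23.6, 20.7 and 20.9 M in the control libraries labelled Mperf15ko, and to 17.2, 20.1 and 17.6 M in the wounded ones. A check for replicates that hold the same library found none, with a chi-square per gene of 15.6 to 63.1 between replicates of a group, which says nothing of how they were grown, and a lowest correlation of log2 CPM of 0.982. The first principal component held 55.2% of the variance and separated wounded from control thalli, and the second held 24.2% and separated the genotypes. Tak-1 wounded replicate 1 had 10.9% of its reads in its 10 most abundant genes, against 5.5% to 8.60% in the other 11 libraries.

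**Figure D1:**
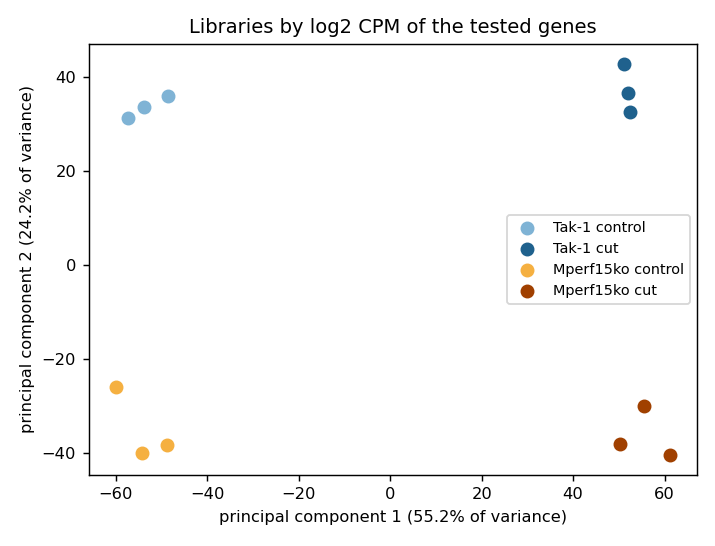
Principal components 1 and 2 of log2 CPM over the tested genes, with 1 point per library, coloured by group, and the percent of variance on each axis (55.2% and 24.2%). The 6 wounded libraries lie apart from the 6 control libraries on component 1, and the genotypes lie apart on component 2.

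The series asks whether the wound-induced transcription factor ERF15 acts in regeneration through the synthesis of oxylipins, signals made from oxidised fatty acids. MpERF15 (Mp7g09350), an AP2/ERF factor and the gene named in the mutant label, was counted in every library. Its estimated reads were 59, 51 and 54 in Tak-1 control replicates 1 to 3 and 458, 1029 and 1087 in wounded Tak-1. They were 60, 92 and 46 in control thalli labelled Mperf15ko and 383, 531 and 911 in the wounded ones. MpERF15 rose after wounding in Tak-1 from 2.16 ± 0.287 to 38.4 ± 10.1 CPM (log2 fold change 4.17, SE 0.374, edgeR adjusted p = 3.6e-06), and in Mperf15ko from 3.04 ± 1.18 to 33.4 ± 14.9 CPM (3.46, SE 0.364, adjusted p = 1.4e-05). Its level did not pass the test between the genotypes in control thalli (0.50, SE 0.42, adjusted p = 0.41) or wounded thalli (-0.20, SE 0.30, adjusted p = 0.66), nor did the difference between its responses (-0.70, SE 0.52, adjusted p = 0.67). Counts over the whole transcript therefore do not check the genotype label, and every genotype direction that follows rests on that label.

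The first comparison asked which genes responded to wounding in Tak-1 within 1 h. Among the genes that rose were the lipoxygenases MpLOX1, MpLOX2, MpLOX4, MpLOX6, MpLOX8 and MpLOX10, the CYP74 gene MpCYP74N2, and MpJAZ, which encodes the repressor of oxylipin signalling. WRKY and NAC factors, LEA genes, chalcone synthase-type polyketide synthases and PP2C phosphatases passed camera upward as lists with a preset correlation, and peroxidases and MCM replication genes downward. These list calls were lost with an estimated correlation (adjusted p of 0.11 to 0.78). Of 14246 genes, 6582 passed the test, 3336 higher and 3246 lower, and 1596 rose and 454 fell by 2-fold or more. Called genes were 50.7% higher with TMM and 36.2% higher with upper quartile scaling, which shifted the median of all genes by -0.134.

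Lipoxygenases oxygenate polyunsaturated fatty acids at the first step of oxylipin synthesis. In Tak-1, 6 of 15 tested members rose, 4 fell and 5 did not pass, with the same counts adjusted over the list alone. The list did not pass camera (adjusted p = 0.25, and adjusted p = 0.76 with an estimated correlation), and its median was -0.028 where its test pointed upward. MpLOX2 (Mp2g23380) went from 120 ± 8.67 to 675 ± 55.7 CPM (log2 fold change 2.49, SE 0.11, adjusted p = 3.8e-10). MpLOX1 (Mp2g00660) went from 16.5 ± 2.53 to 104 ± 22 CPM (2.65, SE 0.15, adjusted p = 5e-09) and MpLOX4 (Mp5g21680) from 14.6 ± 4.57 to 68.4 ± 16.4 CPM (2.23, SE 0.21, adjusted p = 2.7e-06). MpLOX8 rose by 2.13 (SE 0.26), MpLOX10 by 1.22 (SE 0.15) and MpLOX6, at 0.483 ± 0.337 CPM in control thalli, to 3.55 ± 2.03 CPM. MpLOX14, the most abundant of those that fell, went from 293 ± 21.4 to 132 ± 8.38 CPM (-1.15, SE 0.12), and MpLOX16 changed by -1.19 (SE 0.17). MpLOX12 changed by -0.86 (SE 0.24, adjusted p = 0.0095), or by -0.60 without Tak-1 control replicate 2, which ended its call. MpLOX11 changed by -0.61 (SE 0.19, adjusted p = 0.018), and its call ended without Tak-1 control replicate 2 (-0.50) or 3 (-0.51) or wounded replicate 1 (-0.53) or 2 (-0.55).

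CYP74 enzymes convert fatty acid hydroperoxides. MpCYP74N2 (Mp5g16260) went from 73.4 ± 6.34 to 162 ± 46.7 CPM in Tak-1 (log2 fold change 1.15, SE 0.23, adjusted p = 0.0016), and MpCYP74N1 (Mp3g21350), at 34.0 ± 3.90 and 30.1 ± 2.53 CPM, did not pass. MpJAZ (Mp6g06230), the single TIFY gene, went from 25.8 ± 2.27 to 144 ± 8.39 CPM (2.48, SE 0.0865, adjusted p = 8e-11). Among the oxylipin genes, MpLOX2, MpLOX4, MpLOX9, MpLOX11 to MpLOX13, MpJAZ and the CYP74 genes had whole counts, and the other lipoxygenases shared reads with similar transcripts.

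**Figure D2:**
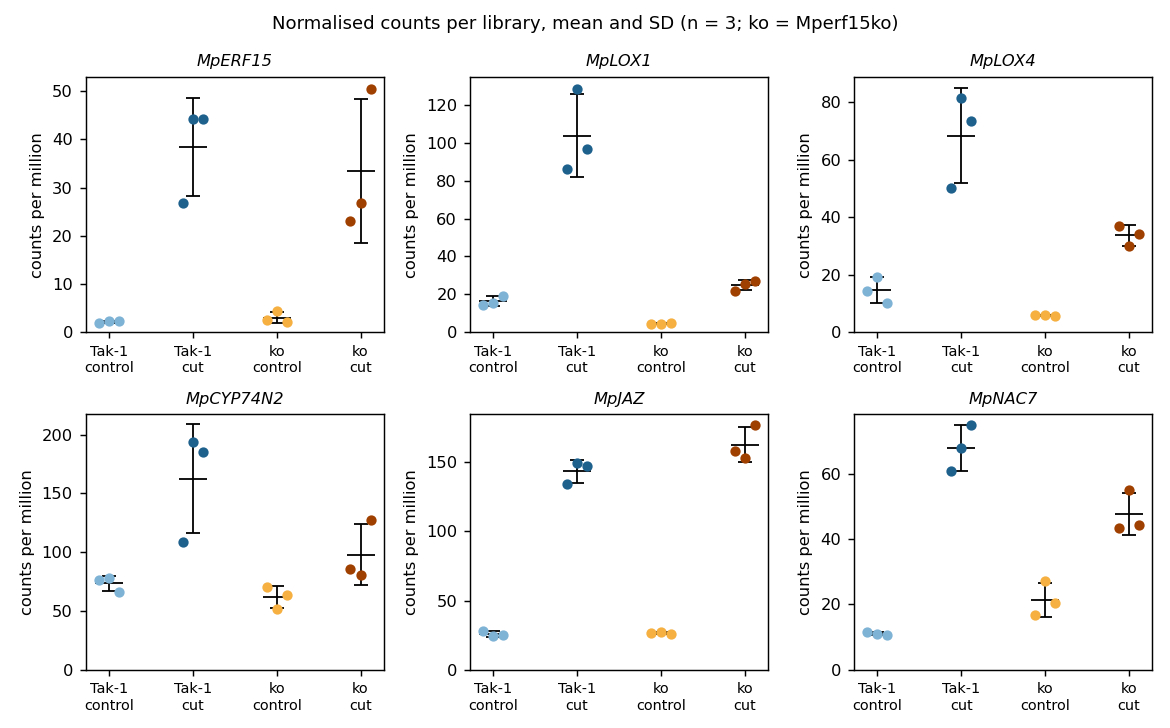
CPM per library (points, linear axis) of MpERF15, MpLOX1, MpLOX4, MpCYP74N2, MpJAZ and MpNAC7 in the 4 groups, with the mean and SD of 3 libraries. MpERF15 and MpJAZ rose in both genotypes, while MpLOX1 stood at 16.5 CPM in Tak-1 and 4.66 CPM in Mperf15ko control thalli and at 104 and 24.9 CPM after wounding.

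Among transcription factor lists, WRKY and NAC passed camera upward in Tak-1 with the preset correlation, and AP2/ERF and bHLH did not pass. All 13 tested WRKY genes were higher, over all genes and adjusted over the list alone (median log2 fold change 1.51, camera adjusted p = 2.2e-10, and adjusted p = 0.11 with an estimated correlation). MpWRKY14 went from 8.69 ± 1.24 to 106 ± 3.12 CPM and MpWRKY7 from 1.21 ± 0.481 to 11.5 ± 1.51 CPM. Of 8 NAC genes 6 rose and 0 fell, also adjusted over the list alone (median 0.88, camera adjusted p = 9.7e-05, and adjusted p = 0.35 with an estimated correlation). MpNAC4 went from 85.9 ± 5.03 to 420 ± 33.6 CPM and MpNAC7 from 11 ± 0.384 to 67.9 ± 7 CPM. The AP2/ERF list had 9 members higher and 5 lower of 22, also adjusted over the list alone, without passing camera (adjusted p = 0.30, and adjusted p = 0.76 with an estimated correlation). In it MpERF21 went from 0.233 ± 0.167 to 87.0 ± 11.5 CPM. The bHLH list had 11 higher and 12 lower of 37, also adjusted over the list alone (adjusted p = 0.17, and adjusted p = 0.76 with an estimated correlation), and held MpBHLH51, which went from 0.403 ± 0.222 to 140 ± 7.62 CPM, and MpBHLH4, which went from 3.60 ± 1.5 to 205 ± 12.7 CPM.

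LEA genes, of a family whose proteins often accumulate in drying tissues, were added as a list from the symbols. In Tak-1 they were higher in 49 and lower in 5 of 65 members, also adjusted over the list alone. Their median log2 fold change was 2.17 (camera adjusted p = 1.3e-10, and adjusted p = 0.35 with an estimated correlation). MpLEA-like14 went from 2.62 ± 1.03 to 78.9 ± 9.57 CPM. Polyketide synthases of the chalcone synthase type were higher in 11 and lower in 4 of 21 (11 and 5 adjusted over the list alone, camera adjusted p = 0.014, and adjusted p = 0.76 with an estimated correlation). MpPKS/CHS21 went from 17.2 ± 3.17 to 235 ± 18.4 CPM and MpPKS/CHS18 from 21.5 ± 6.78 to 216 ± 19.7 CPM. PP2C phosphatases were higher in 11 and lower in 2 of 19 (12 and 2 adjusted over the list alone, camera adjusted p = 0.0054, and adjusted p = 0.76 with an estimated correlation). MpPP2C_F1 went from 34.7 ± 2.02 to 371 ± 41.8 CPM. Phenylalanine ammonia-lyases, the entry to phenylpropanoids, were higher in 5 and lower in 2 of 10, also adjusted over the list alone, without passing camera (adjusted p = 0.30), and MpPAL7 went from 7.41 ± 1.69 to 68.4 ± 8.92 CPM. Dirigent genes (20 higher and 5 lower of 51, or 20 and 6 adjusted over the list alone, median -0.009) and polyphenol oxidases (11 and 5 of 42, or 11 and 2 adjusted over the list alone, median -0.11) had negative medians where their tests pointed upward, neither passing camera (adjusted p = 0.068 and adjusted p = 0.11, and adjusted p = 0.76 and adjusted p = 0.78 with an estimated correlation). In these lists MpDIR39 went from 2.42 ± 1.11 to 159 ± 26.4 CPM and MpPPO2 from 1.57 ± 0.366 to 55.7 ± 5.58 CPM.

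Peroxidases were lower in 52 and higher in 10 of 125 members in Tak-1 (55 and 10 adjusted over the list alone, median log2 fold change -0.69, camera adjusted p = 0.014, and adjusted p = 0.78 with an estimated correlation). Genes of the MCM helicase, which opens DNA for replication, were lower in 8 and higher in 0 of 10, also adjusted over the list alone (median -0.61, camera adjusted p = 0.041, and adjusted p = 0.76 with an estimated correlation). MpMCM6 went from 10.1 ± 1.41 to 3.73 ± 0.5 CPM. Of 4 cyclins 2 fell, MpCYCD_1 (-0.73, SE 0.18, adjusted p = 0.0036) and MpCYCB_1 (-0.75, SE 0.17, adjusted p = 0.0019). Expansins, which loosen cell walls, were lower in 14 and higher in 6 of 36 (15 and 6 adjusted over the list alone) without passing camera (adjusted p = 0.11). In that list MpExpansin6 went from 324 ± 23.7 to 71.1 ± 9.43 CPM and MpEXL1 from 57.3 ± 7.63 to 9.02 ± 0.189 CPM. Other genes that fell were Mp7g05640 (219 ± 33.3 to 25.7 ± 1.45 CPM), Mp1g07670 (101 ± 9.75 to 14.6 ± 2.14 CPM) and MpCYP78-like1 (39.2 ± 9.85 to 4.99 ± 0.221 CPM). Of 8 tested cell type markers 5 rose and 0 fell in Tak-1 (4 and 0 with upper quartile scaling), and 4 rose and 0 fell in Mperf15ko. MpGCAM1, listed for gemma cups, rose by 2.48 (SE 0.28) in Tak-1 and 3.16 (SE 0.31) in Mperf15ko. MpSYP13A and MpNOP1, listed for air chambers, rose by 0.89 (SE 0.0859) and 0.55 (SE 0.11) in Tak-1 and by 0.98 (SE 0.0861) and 0.40 (SE 0.11) in Mperf15ko, where the call of MpNOP1 ended without control replicate 1 (0.33). The germ line marker MpDUO1 rose from 0.565 ± 0.255 to 1.66 ± 0.185 CPM in Tak-1 and from 0.809 ± 0.0847 to 2.53 ± 0.417 CPM in Mperf15ko. MpSYP13B rose in Tak-1 by 0.50 (SE 0.17, adjusted p = 0.023), a call that ended with upper quartile scaling (0.36), with transcripts as features (0.52), and without Tak-1 control replicates 2 (0.48) or 3 (0.40) or wounded replicate 3 (0.43).

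The next comparison asked how thalli labelled Mperf15ko responded to wounding. Among 15 lipoxygenases 6 rose, 2 fell and 7 were not called, and of the 2 CYP74 genes 1 rose and 1 fell. MpLOX2 went from 115 ± 13.3 to 866 ± 88.5 CPM, MpLOX1 from 4.66 ± 0.318 to 24.9 ± 2.56 CPM and MpJAZ from 26.6 ± 0.635 to 163 ± 12.4 CPM. WRKY, NAC and LEA genes, polyketide synthases and PP2C phosphatases again passed camera upward with a preset correlation, together with dirigent and GST genes, and peroxidases and MCM genes downward. With an estimated correlation these list calls were lost (adjusted p of 0.19 to 0.81). In all, 6210 genes passed, 3342 higher and 2868 lower, and 1556 rose and 487 fell by 2-fold or more. Called genes were 53.8% higher with TMM and 39.3% higher with upper quartile scaling, which shifted the median by -0.118. Called in both genotypes were 2709 higher genes, where independent lists would share 782.6, and 2222 lower genes, where they would share 653.5. The log2 fold changes correlated at 0.873 across genes, which are not independent replicates, and 10 genes were called in opposite directions, 5 of them higher in Tak-1 and 5 lower.

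In Mperf15ko 6 lipoxygenases rose and 2 fell of 15, also adjusted over the list alone (camera adjusted p = 0.090, and adjusted p = 0.60 with an estimated correlation). MpLOX2 rose by 2.91 (SE 0.11, adjusted p = 1.1e-10), MpLOX4 by 2.50 (SE 0.23), MpLOX1 by 2.42 (SE 0.17), MpLOX8 by 1.96 (SE 0.29) and MpLOX10 by 1.42 (SE 0.15). MpLOX14 changed by -1.03 (SE 0.12) and MpLOX16 by -1.51 (SE 0.17). MpJAZ rose by 2.61 (SE 0.0872, adjusted p = 5.1e-11). MpLOX6 rose to 2.81 ± 0.896 CPM (2.09, SE 0.72, adjusted p = 0.032), and this call ended without Mperf15ko control replicate 1 (2.04) or 3 (1.55) or wounded replicate 1 (1.94) or 2 (1.94). Without control replicate 2 the change was 2.96. The call of MpCYP74N2 (61.7 ± 9.57 to 97.9 ± 25.8 CPM, 0.67, SE 0.23, adjusted p = 0.036) was lost in 12 of 25 alternatives. Its values were 0.41 without Mperf15ko wounded replicate 3, 0.76, 0.54 and 0.67 without control replicates 1, 2 and 3 of that line, and 0.66, 0.65 and 0.65 without Tak-1 control replicates 1, 2 and 3. MpCYP74N1 changed by -0.34 (SE 0.13, adjusted p = 0.045), and its call ended without Mperf15ko control replicate 2 (-0.38) or 3 (-0.29) or wounded replicate 3 (-0.22).

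WRKY genes were higher in 11 and lower in 0 of 13 in Mperf15ko, also adjusted over the list alone (camera adjusted p = 7.3e-08, and adjusted p = 0.19 with an estimated correlation). NAC genes were higher in 4 and lower in 0 of 8, also adjusted over the list alone (adjusted p = 0.026, and adjusted p = 0.60 with an estimated correlation). LEA genes were higher in 44 and lower in 6 of 65 (48 and 6 adjusted over the list alone, camera adjusted p = 2.1e-09, and adjusted p = 0.60 with an estimated correlation). Polyketide synthases were higher in 12 and lower in 3 of 21 (adjusted p = 0.017) and dirigent genes in 21 and 5 of 51 (adjusted p = 0.018), both also adjusted over the list alone and both with adjusted p = 0.60 with an estimated correlation. GST genes were higher in 14 and lower in 4 of 33 (14 and 5 adjusted over the list alone, adjusted p = 0.030, and adjusted p = 0.60 with an estimated correlation). PP2C genes were higher in 9 and lower in 3 of 19, also adjusted over the list alone (adjusted p = 0.027, and adjusted p = 0.63 with an estimated correlation). Peroxidases were lower in 41 and higher in 11 of 125 (adjusted p = 0.017, and adjusted p = 0.81 with an estimated correlation) and MCM genes were lower in 8 and higher in 0 of 10 (adjusted p = 0.026, and adjusted p = 0.60 with an estimated correlation). Among single genes, MpWRKY10 went from 8.67 ± 2.46 to 67.3 ± 11.4 CPM, MpNAC3 from 223 ± 46.2 to 549 ± 33.0 CPM, MpLEA-like14 from 0.169 ± 0.0607 to 112 ± 11.6 CPM and MpDIR39 from 0.381 ± 0.0939 to 84.5 ± 9.90 CPM. MpGST35 went from 83.4 ± 6.71 to 523 ± 63.5 CPM, and MpCYP815A1, a cytochrome P450, from 13.6 ± 2.56 to 504 ± 29.4 CPM. MpGH3A, of the family that conjugates auxin, went from 62.3 ± 5.10 to 320 ± 37.5 CPM, and MpMCM6 from 7.45 ± 0.719 to 2.37 ± 0.443 CPM.

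The third comparison asked what differed between the genotypes before wounding. Control thalli labelled Mperf15ko had lower transcripts of phenylpropanoid and defence families: polyphenol oxidases, polyketide synthases, phenylalanine ammonia-lyases, chitinases and thaumatins, PR1, dirigent, peroxidase and LEA genes. These list calls and that of the lipoxygenases were lost with an estimated correlation (adjusted p of 0.052 to 0.37). Of the lipoxygenases, MpLOX1 was at 4.66 ± 0.318 against 16.5 ± 2.53 CPM and MpLOX4 at 5.95 ± 0.185 against 14.6 ± 4.57 CPM. Lists that passed upward with the preset correlation were PP2C, bHLH, NAC, pectin methylesterase and protein kinase genes, and these calls too were lost with the estimated one (adjusted p of 0.36 to 0.53). In all, 4010 genes passed, 1931 higher and 2079 lower in Mperf15ko, and 216 were higher and 715 lower by 2-fold or more. The count was 2565 without Mperf15ko control replicate 3. Called genes were 48.2% higher, and 39.8% with upper quartile scaling.

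**Figure D3:**
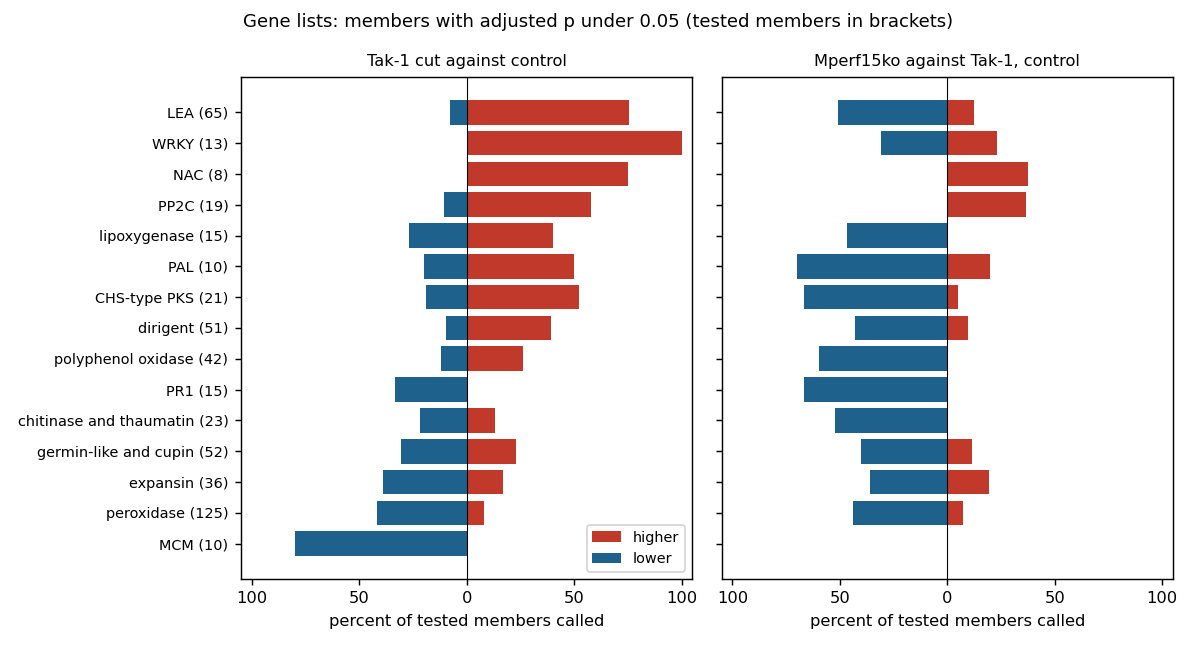
Percent of tested members called higher (right) and lower (left) for 15 gene lists, in the wound response of Tak-1 and in control thalli labelled Mperf15ko against Tak-1. WRKY genes rose with wounding in 13 of 13 members, and polyphenol oxidases were lower in Mperf15ko controls in 25 of 42.

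Among enzymes of phenolic metabolism, polyphenol oxidases were lower in 25 and higher in 0 of 42 (27 and 0 adjusted over the list alone, median log2 fold change -1.07, camera adjusted p = 2e-13, and adjusted p = 0.064 with an estimated correlation). MpPPO52 stood at 0.354 ± 0.220 against 5.55 ± 1.87 CPM. Polyketide synthases were lower in 14 and higher in 1 of 21, also adjusted over the list alone (median -1.04, camera adjusted p = 2.2e-12, and adjusted p = 0.052 with an estimated correlation). MpPKS/CHS11 stood at 0.414 ± 0.224 against 7.46 ± 2.43 CPM and MpPKS/CHS13 at 0.679 ± 0.212 against 11.4 ± 3.73 CPM. Phenylalanine ammonia-lyases were lower in 7 and higher in 2 of 10 (8 and 2 adjusted over the list alone, median -1.38, camera adjusted p = 9.5e-08, and adjusted p = 0.052 with an estimated correlation). MpPAL3 stood at 0.786 ± 0.377 against 12.6 ± 3.94 CPM and MpPAL7 at 1.35 ± 0.689 against 7.41 ± 1.69 CPM. Dirigent genes, whose proteins direct the coupling of phenolic radicals, were lower in 22 and higher in 5 of 51 (23 and 5 adjusted over the list alone, camera adjusted p = 1.2e-06, and adjusted p = 0.059 with an estimated correlation). MpDIR33 stood at 0.650 ± 0.111 against 5.99 ± 1.29 CPM. Peroxidases were lower in 55 and higher in 9 of 125 (59 and 9 adjusted over the list alone, camera adjusted p = 1.2e-06, and adjusted p = 0.37 with an estimated correlation). MpPOD89 stood at 4.46 ± 1.56 against 64.0 ± 18.9 CPM (-3.83, SE 0.30, adjusted p = 2.1e-05). The counts of the polyphenol oxidases, polyketide synthases, ammonia-lyases and dirigent genes named here were fractional, and MpPOD89 had whole counts.

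Chitinases and thaumatins, which act on fungal walls or accumulate in infected tissue, were lower in 12 and higher in 0 of 23 (14 and 0 adjusted over the list alone, camera adjusted p = 2.8e-10, and adjusted p = 0.052 with an estimated correlation). PR1 genes were lower in 10 and higher in 0 of 15 (11 and 0 adjusted over the list alone, camera adjusted p = 3e-08, and adjusted p = 0.052 with an estimated correlation). MpGH19.13 stood at 9.50 ± 1.43 against 77.8 ± 20.4 CPM (-3.04, SE 0.19, adjusted p = 2.4e-06) and MpPR1o at 2.25 ± 0.699 against 20.8 ± 7.13 CPM (-3.21, SE 0.28, adjusted p = 1.4e-05). LEA genes were lower in 33 and higher in 8 of 65 (36 and 11 adjusted over the list alone, camera adjusted p = 4.9e-05, and adjusted p = 0.36 with an estimated correlation). Lower too were germin-like and cupin genes in 21 and 6 of 52 (23 and 6 adjusted over the list alone, adjusted p = 0.00047), and GST genes in 13 and 1 of 33 (15 and 2 adjusted over the list alone, adjusted p = 0.012), both with adjusted p = 0.36 with an estimated correlation. MpPR15c, a germin-like gene, stood at 0.177 ± 0.102 against 4.98 ± 2.24 CPM and MpGST17 at 42.8 ± 4.45 against 78.5 ± 3.39 CPM. Cytochrome P450 genes were lower in 25 and higher in 7 of 93 (30 and 7 adjusted over the list alone, adjusted p = 0.0097, and adjusted p = 0.24 with an estimated correlation). MpCYP716Z1 stood at 8.50 ± 1.15 against 30.3 ± 8.70 CPM. Of 5 HSP90 genes 2 were lower and 0 higher (adjusted p = 0.043, and adjusted p = 0.39 with an estimated correlation). MpHSP90-2 was lower by -0.43 (SE 0.10) and MpHSP90-4 by -0.45 (SE 0.10). Counts of MpGH19.13, MpPR15c and MpCYP716Z1 were fractional, and those of MpPR1o, MpGST17 and these 2 HSP90 genes were whole.

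Lipoxygenases were lower in 7 and higher in 0 of 15 in Mperf15ko controls (7 and 1 adjusted over the list alone, camera adjusted p = 0.0037, and adjusted p = 0.18 with an estimated correlation). MpLOX11 stood at 2.03 ± 0.265 against 8.83 ± 1.66 CPM (-2.12, SE 0.21, adjusted p = 2.1e-05). MpLOX1 was lower by a log2 fold change of -1.82 (SE 0.17, adjusted p = 1.4e-05), MpLOX4 by -1.29 (SE 0.23, adjusted p = 0.0019), MpLOX10 by -0.62 (SE 0.15) and MpLOX14 by -0.59 (SE 0.12). MpLOX8 (-0.96, SE 0.29, adjusted p = 0.024) was not called without Tak-1 control replicate 3 (-0.92) or Mperf15ko control replicate 3 (-0.69). MpLOX5 (-0.88, SE 0.30, adjusted p = 0.040) was not called without Tak-1 control replicates 2 (-0.89) or 3 (-0.69), Mperf15ko control replicates 1 (-0.90), 2 (-0.94) or 3 (-0.74), Tak-1 wounded replicate 3 (-0.86) or Mperf15ko wounded replicate 2 (-0.86). MpLOX2 (-0.06, SE 0.10), MpCYP74N2 (-0.25, SE 0.23) and MpJAZ (0.05, SE 0.0858) did not pass.

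Lists higher in Mperf15ko controls were PP2C genes (7 higher and 0 lower of 19, also adjusted over the list alone, camera adjusted p = 0.0039), pectin methylesterases (4 and 1 of 11, adjusted p = 0.036) and bHLH genes (13 and 4 of 37, or 16 and 4 adjusted over the list alone, adjusted p = 0.032). Higher too were NAC genes (3 and 0 of 8, or 4 and 1 adjusted over the list alone, adjusted p = 0.043) and protein kinases (26 and 11 of 140, or 25 and 11 adjusted over the list alone, adjusted p = 0.043). With an estimated correlation the PP2C and pectin methylesterase lists had adjusted p = 0.36, the bHLH and NAC lists adjusted p = 0.37 and the kinases adjusted p = 0.53. MpPP2C_F3 stood at 22.6 ± 4.39 against 9.76 ± 1.65 CPM, MpNAC2 at 70.9 ± 13.2 against 31.7 ± 4.67 CPM and MpBHLH31 at 31.3 ± 5.61 against 15.2 ± 1.69 CPM. MpPIN4, of the family of auxin efflux carriers, was at 2.17 ± 0.244 against 17 ± 2.5 CPM (-2.97, SE 0.15, adjusted p = 1.8e-07), with whole counts. Of the 8 cell type markers 2 were lower and 0 higher (1 lower adjusted over the list alone). MpGCAM1 was lower by -0.93 (SE 0.33, adjusted p = 0.047), a call lost in 17 of 25 alternatives, 10 of which left out 1 library, with -0.44 without Tak-1 control replicate 1, -1.002, -1.06 and -0.71 without Mperf15ko control replicates 1, 2 and 3, and -0.91 without each of the 6 wounded libraries. MpBHLH14, the rhizoid regulator RSL1, was lower by -0.64 (SE 0.15, adjusted p = 0.0059), and the oil body markers MpSYP12B (-0.28, SE 0.30) and MpERF13 (-0.49, SE 0.46) did not pass. Of 61 tested genes on the V chromosome, the male sex chromosome, 7 were higher and 3 lower, and every library had 0.899% to 3.17% of its reads on them.

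In wounded thalli the comparison asked which genotype differences were present 1 h after the injury. Polyphenol oxidase, polyketide synthase, ammonia-lyase, chitinase and thaumatin, PR1, dirigent, peroxidase, LEA and lipoxygenase lists again passed camera downward with a preset correlation. These calls were lost with an estimated correlation (adjusted p of 0.057 to 0.50). MpLOX1 was at 24.9 ± 2.56 against 104 ± 22 CPM and MpLOX4 at 33.7 ± 3.54 against 68.4 ± 16.4 CPM. MpLOX2 and MpJAZ did not share this direction, at 866 ± 88.5 against 675 ± 55.7 CPM and at 163 ± 12.4 against 144 ± 8.39 CPM. In all, 3352 genes passed, 1685 higher and 1667 lower, and 257 were higher and 735 lower by 2-fold or more. The count was 1832 without Tak-1 wounded replicate 2, 2210 without Tak-1 wounded replicate 3 and 2096 without Mperf15ko wounded replicate 2. Control and wounded comparisons shared 863 higher genes, where independent lists would share 228.4, and 1138 lower genes, where they would share 243.3. Of the others, 46 genes were called in opposite directions (25 higher and 21 lower in controls), and log2 fold changes correlated at 0.738 across genes.

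Polyketide synthases were lower in 12 and higher in 1 of 21 in wounded Mperf15ko (12 and 2 adjusted over the list alone, camera adjusted p = 1.6e-12, and adjusted p = 0.062 with an estimated correlation). Polyphenol oxidases were lower in 19 and higher in 1 of 42 (20 and 1 adjusted over the list alone, adjusted p = 1.1e-12, and adjusted p = 0.11 with an estimated correlation). Ammonia-lyases were lower in 7 and higher in 0 of 10 (8 and 1 adjusted over the list alone, adjusted p = 7.1e-11) and chitinases and thaumatins in 10 and 0 of 23 (11 and 0 adjusted over the list alone, adjusted p = 4e-09), both with adjusted p = 0.057 with an estimated correlation. PR1 genes were lower in 9 and higher in 0 of 15, also adjusted over the list alone (adjusted p = 1.7e-07, and adjusted p = 0.057 with an estimated correlation). Peroxidases were lower in 49 and higher in 10 of 125 (55 and 11 adjusted over the list alone, adjusted p = 1.3e-06, and adjusted p = 0.50 with an estimated correlation). LEA genes were lower in 30 and higher in 5 of 65 (30 and 6 adjusted over the list alone, adjusted p = 3.3e-06, and adjusted p = 0.30 with an estimated correlation) and dirigent genes were lower in 19 and higher in 7 of 51 (22 and 10 adjusted over the list alone, adjusted p = 0.00016, and adjusted p = 0.13 with an estimated correlation). Germin-like and cupin genes were lower in 16 and higher in 7 of 52 (18 and 7 adjusted over the list alone, adjusted p = 0.019, and adjusted p = 0.54 with an estimated correlation). P450 genes were lower in 20 and higher in 7 of 93 (21 and 8 adjusted over the list alone, adjusted p = 0.028, and adjusted p = 0.30 with an estimated correlation). Pectin methylesterases were higher in 4 and lower in 0 of 11, also adjusted over the list alone (adjusted p = 0.010, and adjusted p = 0.30 with an estimated correlation) and bHLH genes in 11 and 0 of 37 (12 and 0 adjusted over the list alone, adjusted p = 0.032, and adjusted p = 0.50 with an estimated correlation).

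Examples in wounded thalli were MpPKS/CHS12 at 4.72 ± 1.22 against 49.6 ± 9.98 CPM, MpPPO3 at 3.13 ± 1.00 against 30.2 ± 8.18 CPM, MpPAL3 at 1.98 ± 0.467 against 22.7 ± 4.54 CPM and MpPR15h at 3.46 ± 0.600 against 39.8 ± 9.39 CPM, all with fractional counts. MpGH19.13, also with fractional counts, was at 9.69 ± 1.80 against 82.6 ± 5.72 CPM. With whole counts, MpPOD89 was at 7.82 ± 2.22 against 99.3 ± 16.6 CPM and MpPIN4 at 1.76 ± 0.0743 against 26.2 ± 2.77 CPM (log2 fold change -3.89, SE 0.16, adjusted p = 1e-08). Mp7g02900, with fractional counts, was at 224 ± 43.4 against 5682 ± 416 CPM, and Mp7g01940 was higher, at 3304 ± 1210 against 326 ± 15.2 CPM. MpCYP707A, of the P450 family that inactivates abscisic acid in other plants, was at 71.9 ± 27.6 against 13.0 ± 0.658 CPM (2.47, SE 0.40, adjusted p = 0.0021).

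Of 15 lipoxygenases 6 were lower and 2 higher in wounded Mperf15ko (7 and 2 adjusted over the list alone, camera adjusted p = 0.028, and adjusted p = 0.30 with an estimated correlation). MpLOX1 was lower by a log2 fold change of -2.06 (SE 0.15, adjusted p = 1.4e-06), MpLOX11 by -1.71 (SE 0.22), MpLOX8 by -1.13 (SE 0.25), MpLOX4 by -1.02 (SE 0.20, adjusted p = 0.0041) and MpLOX14 by -0.46 (SE 0.12), and MpLOX7 was higher by 1.08 (SE 0.22). MpLOX5 (-1.05, SE 0.29, adjusted p = 0.020) was not called without Tak-1 wounded replicate 2 (-0.86) or Mperf15ko wounded replicate 2 (-1.10) or 3 (-0.85). MpLOX2 (0.36, SE 0.10, adjusted p = 0.022) was not called without Tak-1 wounded replicate 1 (0.27), 2 (0.39) or 3 (0.36) or Mperf15ko wounded replicate 1 (0.33) or 3 (0.27). MpCYP74N2 was lower by -0.73 (SE 0.23, adjusted p = 0.039), a call lost in 12 of 25 alternatives, with -0.61 and -0.65 without Tak-1 wounded replicates 2 and 3, and -0.66 and -0.63 without Mperf15ko wounded replicates 1 and 2. It was also lost without Tak-1 control replicate 1 (-0.73) or 2 (-0.75) or Mperf15ko control replicate 3 (-0.75).

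The difference between the wound responses tests whether the response depends on the genotype. It was called for 152 genes, 57 with a higher and 95 with a lower response in Mperf15ko, while 1714 genes had an unadjusted p under 0.05. The lipoxygenase, CYP74 and TIFY genes did not pass with edgeR. Their values were -0.23 (SE 0.22) for MpLOX1, 0.42 (SE 0.15, adjusted p = 0.22) for MpLOX2, 0.27 (SE 0.31) for MpLOX4, -0.48 (SE 0.32, adjusted p = 0.63) for MpCYP74N2 and 0.14 (SE 0.12) for MpJAZ. Before adjustment, MpLOX2 alone among these 18 genes passed 0.05 in edgeR. Among the 95 genes with a lower response, 52 rose in both genotypes, 27 rose in Tak-1 and were not called in Mperf15ko, and 11 fell in Mperf15ko and were not called in Tak-1. Among the 57 with a higher response, 37 rose in both and 10 were called, higher, in Mperf15ko and not in Tak-1.

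Lower responses in Mperf15ko included MpRLK-Pelle_L-LEC28, a lectin receptor-like kinase that went from 2.65 ± 0.210 to 34.5 ± 4.58 CPM in Tak-1 and from 3.93 ± 0.813 to 5.92 ± 1.14 CPM in Mperf15ko (difference -3.12, SE 0.26, adjusted p = 0.00011). MpNAC7 went from 11 ± 0.384 to 67.9 ± 7 CPM and from 21.4 ± 5.18 to 47.6 ± 6.44 CPM (-1.46, SE 0.21, adjusted p = 0.0069). MpGT8.8, named for a glycosyltransferase family, went from 34.8 ± 2.67 to 132 ± 11.8 CPM in Tak-1 and from 35.9 ± 5.11 to 44.3 ± 4.80 CPM in Mperf15ko (-1.62, SE 0.16, adjusted p = 0.00038). MpCYP97A35 went from 114 ± 5.04 to 279 ± 11.2 CPM and from 125 ± 5.31 to 145 ± 4.58 CPM (-1.08, SE 0.10, adjusted p = 0.00014), and MpMAPKKK10 from 8.76 ± 0.887 to 62.3 ± 9.67 CPM and from 10.9 ± 1.12 to 32.5 ± 0.936 CPM (-1.25, SE 0.17, adjusted p = 0.0041). Higher responses included MpCYP94-like, whose family inactivates jasmonates in flowering plants, which went from 1.87 ± 0.775 to 22.8 ± 3.11 CPM in Tak-1 and from 0.379 ± 0.0774 to 30.2 ± 2.22 CPM in Mperf15ko (2.67, SE 0.37, adjusted p = 0.0048). The difference for MpLEA-like14 was 4.45 (SE 0.45, adjusted p = 0.00078), from a lower control level in Mperf15ko. Counts of MpNAC7, MpGT8.8 and MpMAPKKK10 were fractional, so their values are uncertain, and those of the other genes named here were whole.

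The lists called for the difference between responses were NAC (camera adjusted p = 3.5e-05, median log2 fold change -0.51, 0 higher and 1 lower of 8, or 0 and 4 adjusted over the list alone), and dirigent genes (adjusted p = 0.010, median 0.33, 0 of 51, or 4 higher adjusted over the list alone). Also called were HSP90 (adjusted p = 0.010, median 0.34, 0 of 5, or 2 higher adjusted over the list alone), protein kinase (adjusted p = 0.022, median -0.070, 2 lower of 140, or 4 lower adjusted over the list alone) and core histone genes (adjusted p = 0.029, median 0.17, 0 of 24). With an estimated correlation they had adjusted p = 0.64, adjusted p = 0.69, adjusted p = 0.87, adjusted p = 0.95 and adjusted p = 0.95 in the same order. The count of 152 genes was 61 without Tak-1 wounded replicate 2, 65 without Tak-1 wounded replicate 3, 73 without Mperf15ko control replicate 3, 101 without Tak-1 control replicate 2 and 324 without Mperf15ko control replicate 1. DESeq2 called 470 genes with the same 12 libraries.

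The size of the whole response was compared over genes called by the mean of both responses. The 4087 genes that rose had a median log2 fold change of 0.77 in Tak-1 and 0.74 in Mperf15ko, and the 4199 that fell had medians of -0.48 and -0.45. Scores of the wounded libraries, each minus the mean of its controls, differed by 0.0155 for the genes that rose (1.09 ± 0.0177 in Tak-1, 1.11 ± 0.0509 in Mperf15ko, SD, n = 3, exact permutation p = 0.8) and were -0.561 ± 0.0317 and -0.550 ± 0.0484 for those that fell (exact permutation p = 1). The spread between control libraries enters neither these SDs nor the permutation, so both understate the uncertainty. With 20 arrangements of the 6 wounded libraries the smallest 2-sided p the test allows is 0.1.

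**Figure D4:**
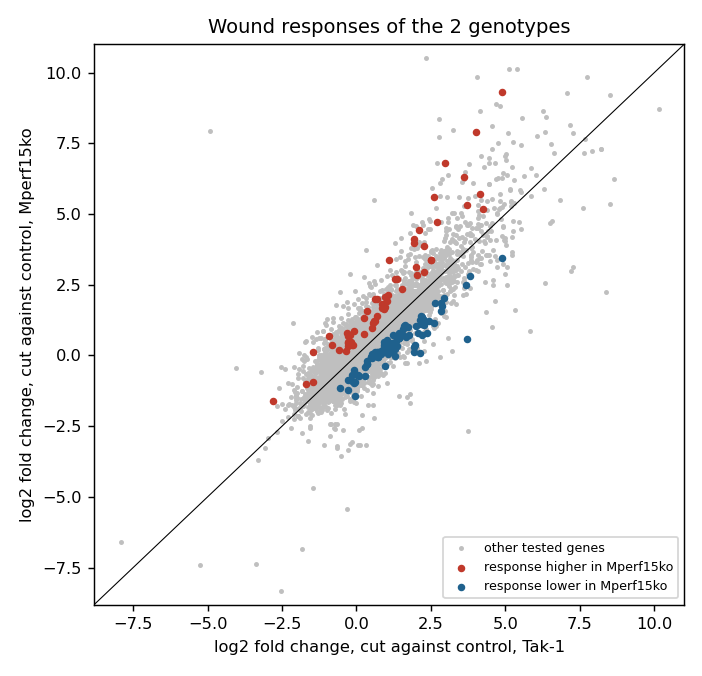
Log2 fold change after wounding in Tak-1 (x axis) against Mperf15ko (y axis), with 1 point per tested gene and the genes called for the difference between the responses in colour. Most genes lie along the diagonal (r = 0.873 across genes), and 152 lie off it by more than the test allows, among them MpRLK-Pelle_L-LEC28 and MpNAC7 below it.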

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

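The tests for wounding or handling of control thalli, split into members that wounding raised and did not raise, for oil body and rhizoid markers, and for a lower starting level were chosen after the result was seen. The difference between the wound responses (Mperf15ko minus Tak-1) passed the test for 152 genes, and 19 named genes among them differed between the genotypes by this test. Higher responses in Mperf15ko were 4.45 for MpLEA-like14, 3.81 for MpPR15c, 2.99 for MpSUT4, 2.67 for MpCYP94-like, 2.35 for Mp5g07510, 2.26 for MpPOD18, 1.58 for MpLEA-like42 and 1.07 for MpFTPSL2 (log2). Lower responses were -3.12 for MpRLK-Pelle_L-LEC28, -2.06 for Mp2g25910, -1.79 for Mp2g01500, -1.62 for MpGT8.8, -1.47 for MpPOD169, -1.46 for MpNAC7, -1.32 for MpDOXC3, -1.25 for MpMAPKKK10, -1.08 for MpCYP97A35, -1.03 for MpERF1 and -1.003 for MpPP2C_F3. Calls were kept in all 24 alternatives for MpLEA-like14, MpPR15c, MpCYP94-like, Mp5g07510, MpRLK-Pelle_L-LEC28, Mp2g01500, MpGT8.8, MpNAC7, MpMAPKKK10 and MpCYP97A35. They were lost in 13 of 24 for Mp2g25910, MpERF1 and MpSUT4, in 12 for MpLEA-like42, in 9 for MpDOXC3 and in 8 for MpFTPSL2. MpPOD18 lost its call in 2, and MpPP2C_F3 and MpPOD169 in 4 and 3 of 23. The sizes of the highest differences moved with the alternatives. They ranged from 3.061 to 4.719 for MpLEA-like14, from 1.758 to 4.351 for MpPR15c and from 0.7732 to 3.313 for MpSUT4. MpLEA-like14 and MpPR15c started from low counts in Mperf15ko controls.

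Among 100 splits of the 12 libraries into 6 and 6, 1 gave as many genes, the real one with 152, and the highest of the others gave 3. A random arrangement of the libraries is thus argued against for this count, at the smallest share that 100 splits allow. The other splits divided libraries of a group, so a shift shared by the 3 libraries of 1 group was not tested. Tak-1 wounded replicate 1, whose reads were the most concentrated in few genes, is argued against as the main source. Without it 136 genes were called, 108 of them among the 152. Those 152 had a median absolute difference of 0.933 without it, against 0.873 with it, and 100% of them kept their direction. They were chosen with that library included, so a kept direction is weak evidence. A lower starting level in control thalli labelled Mperf15ko stays open for part of the genes, since 26.0% (13 of 50) of those with a greater rise there were called lower in its controls and not called between wounded thalli. For MpGT8.8 and MpCYP97A35, whose control levels did not pass the test between the genotypes, a smaller response in Mperf15ko may reflect the genotype, which remains a hypothesis. Counts of MpGT8.8 were fractional, so its values are uncertain, and those of MpCYP97A35 were whole.

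Of 352 tested members of 8 stress and defence lists, with a median log2 fold change of -0.81, 178 were called lower and 25 higher in control thalli labelled Mperf15ko, and the 178 had a median of -1.60 (-1.18 for the 61 with whole counts). Over all 14246 tested genes 2079 were lower and 1931 higher. All 8 lists had passed camera downward in this contrast, while PP2C and NAC lists passed upward, so the count is no separate support. With upper quartile scaling the 178 had -1.65. This cannot decide on a larger share of reads in a few Tak-1 genes, since the scaling moves all genes alike (their median by -0.047). Left uncorrected, such a share would make other genes lower in Tak-1, opposite to this pattern. The planned test of wounding or handling of Tak-1 controls came out as that explanation predicted, a median under -0.5 for the 100 genes with the highest wound response: it was -1.09, and -0.50 without Tak-1 control replicate 3, so a trace of wounding (0.692% of tissue for the 84 of these genes outside the lists) stays open. As the whole cause of the lower lists, wounding with the profile measured at 1 h is argued against by tests chosen afterwards: 58.4% of the 178 members (104) were not raised by wounding, and the 636 genes outside the lists that wounding raised 4-fold or more had a median of -0.0609 (-0.146 to -0.0143 with 1 library left out), where the 15% of wounded tissue that the other 74 members need would give -1.06. Fewer oil body cells or rhizoids cannot be told apart from a genotype effect, with a lowest marker value of -0.644 (MpBHLH14) from 3 markers, and handling with another profile or time course was not tested.

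Among genes called at 2-fold or more, neighbours differed together in control thalli, with 187 adjacent pairs in the same direction against 35.2 by chance, a ratio of 5.32 that was 2.74 at 2 to 5 genes and 1.35 at 6 to 20 genes apart. A long chromosome segment from another parent is argued against as the main cause by a ratio of 1.09 at 21 to 50 genes apart. Set against the upper and lower limits of 200 permutations the ratio was 1.02 and 1.15, which is not a confidence interval. The ratio of 1.09 was above the upper limit of permutations, 1.07 (1.12 against 1.06 in wounded thalli), so a small share from such segments stays open. Shared reads are argued against by 4.87 among genes with whole counts (9256 of 13456 placed genes). The ratio was 24.4 among neighbours with symbols of the same family and 3.65 among those of different families (14 pairs against 3.84). This cannot decide on tandem members of 1 family as the whole cause, since families were told apart by symbol alone. Tandem copies of 2 families can lie interleaved and then count as different, as with MpPAL7 (Mp4g14110) and MpPKS/CHS11 (Mp4g14120). The wound response in Tak-1 had a ratio of 2.44 for adjacent pairs.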

How the results depend on the processing

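The alternatives were planned, and no called value of a named gene changed sign in any of them. Which side held more of the called genes did change, in 2 of 26 alternatives for each wound response (36.2% to 77.9% higher over the alternatives in Tak-1, 39.3% to 76.2% in Mperf15ko), in 15 of 26 for the genotypes in control thalli (23.2% to 54.8%), in 20 of 26 in wounded thalli (25.9% to 51.2%) and in 0 of 25 for the difference between responses. With a 2-fold threshold added, by construction, the counts were 2050 and 2043 for the wound responses of Tak-1 and Mperf15ko, 931 and 992 for the genotypes in control and wounded thalli and 55 for the difference between responses. That difference gave 41 calls with transcripts as features and 470 with DESeq2, and the cause was not tested. With 1 library left out, counts ranged from 2565 (without Mperf15ko control replicate 3) to 4110 for the genotypes in control thalli, from 1832 (without Tak-1 wounded replicate 2) to 3516 in wounded thalli and from 61 (without Tak-1 wounded replicate 2) to 324 (without Mperf15ko control replicate 1) for the difference between responses. Fewer libraries leave less power, and the rise to 324 was not explained. The median of genes that rose differed between genotypes by -0.0266, by -0.085 to -0.0336 with 1 library left out and by 0.0011 with upper quartile scaling, where its sign turned. That of genes that fell differed by 0.0316, by -0.0325 to 0.0484 with 1 library left out and by -0.0134 without a filter. Of the lists, 52 were called by camera with the preset correlation, 0 with the estimated one and 81 by fry. Calls among genes of the male sex chromosome between control thalli went from 10 to 5 with the stricter filter and 6 with only the libraries compared, where fewer genes or libraries entered. With the replicate number as a block the counts were 6224, 5920, 3619, 2926 and 130, and of 18 pairs of libraries with the same number 5 correlated above 0.1 (-0.414 to 0.318), so the numbers did not pair the libraries. Of 371 called results for named genes 296 were called in every alternative that gave a value, and the others lost their call in 430 cases. Trend tests on log2(TPM + 1) shrank folds of low genes by the pseudocount, as for MpPIN4 in control thalli, from -2.97 to -2.07. Between the real groups and other splits of 6 libraries, the real counts were 6582, 6210, 4010 and 3352 and the highest others 2, 0, 0 and 1, with 1 of 10 splits as large each time, too few for a share under 0.05.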

Other observations

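Lists not yet described were counted for the wound response in Tak-1. Auxin genes were higher in 11 and lower in 10 of 27, and 9 and 10 with upper quartile scaling, with MpSAUR8 going from 0.839 ± 0.365 to 15.2 ± 1.19 CPM and MpPIN3, with fractional counts, from 19.6 ± 2.08 to 98.8 ± 16 CPM. ABCG transporters were higher in 8 and lower in 6 of 31 (6 and 9 with upper quartile scaling), R2R3-MYB genes in 5 and 4 of 15 (4 and 6), fatty acid desaturases in 7 and 3 of 14 (1 and 4), pectin methylesterases in 4 and 3 of 11 (3 and 4), protein kinases in 36 and 28 of 140 (33 and 43) and jasmonate signalling genes in 2 and 0 of 4 (1 and 2), so the larger side flipped with that scaling, which shifted the median of all genes by -0.134, and these counts give no direction for the lists. In Mperf15ko 1 of the 4 jasmonate signalling genes rose and 2 fell, with either scaling. Among those that fell was MpCOI1 (-0.30, SE 0.0913, adjusted p = 0.017), which was not called without Mperf15ko control replicate 3 (-0.28) or wounded replicate 1 (-0.19), or with only the libraries compared (-0.28). UGT genes were higher in 5 and lower in 13 of 30 in Tak-1, DOXC genes in 8 and 14 of 29, PPR genes in 14 and 23 of 73 and ASLBD genes in 3 and 1 of 8, also adjusted over the list alone. Adjusted over the list alone the next counts differed, as given in brackets. Terpene synthases were higher in 2 and lower in 2 of 20 (0 and 2) and PR1 genes in 0 and 5 of 15 (0 and 1). Trihelix genes were higher in 7 and lower in 7 of 35 (7 and 6), GST genes in 11 and 7 of 33 (13 and 8) and core histones in 0 and 8 of 24 (0 and 7). None of these lists passed camera in Tak-1, where the jasmonate signalling list was too short to be tested. MpUGT35 went from 45.1 ± 1.96 to 162 ± 18 CPM, MpTRIHELIX23 from 21.7 ± 2.23 to 106 ± 5.87 CPM, MpPPR_43 from 18.7 ± 1.24 to 93 ± 6.48 CPM, MpASLBD24 from 88.2 ± 3.58 to 171 ± 14.8 CPM and MpH2B.3 from 207 ± 11.9 to 116 ± 1.54 CPM.

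In Mperf15ko wounding raised 10 and lowered 7 ABCG genes (8 and 11 with upper quartile scaling), 34 and 31 protein kinases (29 and 40), 15 and 13 germin-like and cupin genes (14 and 15) and 2 and 0 of 5 HSP90 genes (0 and 1), without passing camera. In Tak-1 0 HSP90 genes were higher and 3 lower, also with upper quartile scaling (0 and 3), the list did not pass camera there (adjusted p = 0.46), and the difference between the responses was called for 0 of the 5. Between wounded thalli 15 protein kinases were higher and 12 lower in Mperf15ko, and 10 and 14 with upper quartile scaling. MpABCG3 was at 40.2 ± 3.43 against 19.5 ± 1.74 CPM there, and MpDOXC31 at 25.7 ± 7.01 against 9 ± 2.65 CPM in control thalli. The terpene synthase MpMTPSL2 stood at 0.767 ± 0.251 against 11.6 ± 0.737 CPM in control thalli and at 0.85 ± 0.522 against 8.28 ± 0.281 CPM in wounded thalli.

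Genes that responded to wounding were set against the genotype difference in control thalli. Of 1605 genes that the mean wound response raised 2-fold or more, 283 were lower and 287 higher in Mperf15ko controls (median 0.04), and of 465 genes it lowered 2-fold or more, 138 were lower and 37 higher (median -0.28). Of the other 12176 tested genes, 1658 were lower and 1607 higher. Genes lowered by wounding were thus more often lower in Mperf15ko controls (29.7% against 13.6% of the others) and less often higher (7.96% against 13.2%). Over all tested genes the correlation was -0.00214. In 10 simulations of genes with neither a wound nor a genotype effect its mean was -0.016 (-0.0413 to 0.0214). These hold noise alone, so they cannot decide whether the real effects were related.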
